A study of Escherichia coli with 6 samples.

How the data were processed

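NET-seq libraries were made from 3 WT and 3 ∆SI3* cultures. Per the labels' protocols, cells were filtered, frozen and milled, B. subtilis cells were added as a spike-in in proportion to the E. coli optical density, RNA polymerase carrying a FLAG tag on β′ was pulled down, and an adaptor was ligated to the 3′ ends of the nascent RNA. Per the submitters' processing notes, R 4.1.0, cutadapt, Bowtie, SAMtools and bedtools were used by the authors before deposit. Their order, settings and genome build are not given in the sources used here.

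Each library's file lists 4641652 positions per strand with 3 columns. Per the file headers, the deposited signal columns hold the number of read 3′ ends and the read coverage at each position, and a further column holds their ratio, a fraction made by dividing the former by the latter. The 3′-end signal turned out to be whole reads multiplied by 1 factor per library (1.0562, 0.856 and 0.6977 in WT, 0.7406, 0.5191 and 0.6488 in ∆SI3*), since 100% of values were whole multiples within a tolerance of 0.01. What the factor was scaled to is not given in the sources used here. The coverage column was rebuilt in full as 15 nt for each read, and it and the fraction column were used only as checks. Whole reads recovered in this way numbered from 21427317 to 30690446 per library. Reads were not marked by molecular identifiers in the files, so read floors cover counting error only. B. subtilis reads were not analysed here, and no spike-in scaling was made. Columns of values that belong to no sample numbered 0.

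Groups and replicate numbers came from the sample titles. Pairs of libraries of one strain differed by more than sampling noise (chi-square per gene from 25.6 to 97.8 over 2039 genes), and each library was counted as 1 replicate. Gene names and extents came from the NCBI RefSeq gene table of assembly ASM584v2, whose 4651 genes carry no strand there. Neither files nor labels name a build, so only positions of the deposited files are printed. The match was checked by the read-free stretch of rpoC in ∆SI3*. The 22 rRNA and 86 tRNA genes were left out. A gene got the strand with at least 2 times the reads of the other strand in the mean of all 6 libraries, without regard to strain. This assigned 2040 of 4543 genes (44.9%), and 2503 genes without a strand were left out of the gene tests. Of 53 genes of known strand listed beforehand, 42 were assigned, 42 of them to that strand.

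The tests planned for counts were replaced, because the deposited values are a scaled signal, by limma 3.58.1 in R 4.3.3 on a log2 scale, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Sense reads were summed per gene and converted to CPM with TMM factors, and log2(CPM + 1) was tested, so that changes of low genes are understated. The filter on low values removed no gene. The quasi-likelihood test of edgeR 4.0.16 on the recovered reads was added as an alternative and called 632 genes higher and 607 lower. Of 25 gene lists fixed before the data were examined, the 21 with at least 5 measured genes were tested with camera. The lists were ribosomal proteins, RNA polymerase with sigma and elongation factors, aminoacyl-tRNA synthetases, heat shock, cold shock, RpoS general stress, envelope stress, SOS response, oxidative stress, flagella and chemotaxis, amino acid operons with attenuators, arginine with methionine and cysteine biosynthesis, purine and pyrimidine genes, glycolysis, TCA cycle, ATP synthase with NADH dehydrogenase, anaerobic respiration, iron uptake, lipopolysaccharide operons, prophage genes, catabolite-repressed genes, cell division, nucleoid proteins and leader peptides.

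A pause site was a position with at least 10 reads, at least 4 SD above the mean of the 201 positions centred on it, in windows with a mean of at least 1 read per position. Sites lay on the sense strand of a gene or up to 300 nt upstream of it, at least 100 nt from rRNA and tRNA genes, over 2040768 positions. For numbers of sites, libraries were thinned to 21427317 reads. For relative pause strength, log2 of reads at a site plus 1 over reads in the rest of its window plus 1 was tested at sites called in at least 3 libraries. For neighbouring sites, log2 of downstream over upstream reads was tested per pair. This measure by position alone was chosen after the data were examined, in place of a planned one that needs the genome sequence. The share of reads in the first 150 nt was tested in genes of at least 600 nt with at least 20 reads in each part. The ratio of gene to leader was tested with 0.01 reads per nt added to each, for leaders with at least 20 reads on average. Single values per library were compared with exact permutation tests, two-sided. The floor of the background of a library was estimated as the 5% quantile, over genes of at least 300 nt, of reads per nt on the weaker strand. A background by distance was the median on the weaker strand of genes with few reads, in 5 equal groups of genes by distance from the replication origin.

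Genes named in the text were the 12 largest rises and the 12 largest falls among genes past the threshold whose libraries did not overlap, with at least 50 reads per library on average in the higher strain, together with rpoC and the 4 members of each list with the smallest adjusted p, from which examples were taken. Sites were the 10 largest rises and falls by the same rule, with at most 1 site per gene. Pairs, the his leader position and the genes named for their 5′ share were chosen after their values were seen. Alternatives were other scalings, filters, thresholds, tools and windows, capped positions, a replicate block, and each library left out in turn. Added after the data were examined were other pseudocounts, the deposited scaling, subtraction of the background by its floor and by distance from the origin, stricter windows and site sets, centring of sites, and a strand taken from the leader. DESeq2 1.42.0 was used as a further alternative. Tests needing base sequence (pause consensus, RNA hairpins, base composition, sequence-defined leader and ops sites) were not run.

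The steps were tested on simulated data made from the real means. With a 1.5-fold change, 97.0% of changed genes were recovered in the gene test over 2040 genes, and 5.26% of calls were false. Over 18927 sites, a 2-fold change was recovered at 29.9% of sites and a 4-fold change at 93.9%. Over 1754 pairs, a 4-fold change was recovered in 90.9%. Most simulated sites (18727) and pairs (1554) were unchanged, which makes the adjusted threshold stricter than in the real data. The pause caller found 47% of planted sites of 5-fold height and 99.5% of those of 10-fold height. The other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.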

Results

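The data were NET-seq profiles of Escherichia coli, in which RNA still bound to RNA polymerase is purified and the position of each RNA 3′ end marks where a polymerase stood. Cells with wild-type RNA polymerase (WT, 3 cultures) were compared with cells whose rpoC gene, which encodes the β′ subunit, lacked the SI3 domain and carried a further amino acid change (∆SI3*, 3 cultures). No strain here carried either change alone, so their effects cannot be told apart. SI3 is a lineage-specific insertion in the trigger loop, a mobile part of the active site. The labels call the cultures biological triplicates. Cells grew in rich defined medium with glucose and were harvested at optical densities of 0.45, 0.55 and 0.52 for WT and 0.47, 0.49 and 0.49 for ∆SI3*. The series title states that the comparison asks whether pause profiles differ between the strains. The recovered 3′ ends numbered 24860917, 21427317 and 30690446 in the WT libraries and 22963416, 22080895 and 24841370 in the ∆SI3* libraries. All means below are given ± SD with n = 3 libraries per strain unless stated otherwise, and log2 changes are ∆SI3* over WT.

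The edited gene separated the strains as labelled. In ∆SI3* libraries, a stretch of rpoC codons inside the SI3 coding sequence, fixed before the data were examined, held 0, 2 and 3 sense reads, which is 0, 0.0353 and 0.0647% of the read density of the rest of the gene. A count of 3 reads corresponds to between 0.0529 and 0.0647% in these libraries. In WT libraries the same stretch held 107, 113 and 113% of the density of the rest of the gene. The longest stretch of rpoC almost free of ∆SI3* reads ran from position 4188177 to 4188761 on the + strand, which is 585 nt and codons 943 to 1138. It held 5 reads over the ∆SI3* libraries and 14977 over the WT libraries. Over the whole gene, rpoC signal was 3594 ± 876 CPM (reads scaled to library size) in WT and 3649 ± 699 CPM in ∆SI3*, with a log2 change of 0.03 (limma adjusted p = 0.907). Outside the stretch from codon 943 to 1138 it was 3048 ± 735 and 3648 ± 700 CPM, a log2 change of 0.27 (exact permutation p = 0.4).

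**Figure D1:**
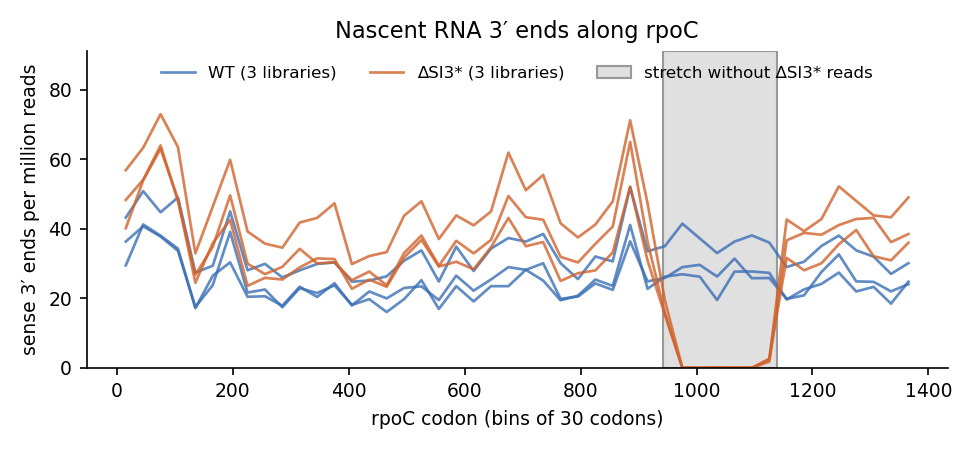
Sense 3′ ends along rpoC in bins of 30 codons (x axis, codon; y axis, reads per bin scaled to library size), 1 line per library, with the stretch from codon 943 to 1138 in grey. The ∆SI3* lines drop to near 0 within the grey stretch, which held 5 reads over 3 libraries, and the WT lines do not. At its edges the bins also hold codons outside it, so the ∆SI3* lines lie above 0 there.

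The libraries also differed away from annotated sense transcription. A background signal lay on both strands. Its floor, taken from the genes with the least reads on their weaker strand and spread over the genome, equalled 26.6 ± 2.25% of reads in WT and 13.7 ± 1.07% in ∆SI3* (exact permutation test, two-sided, p = 0.1). The signal was not flat: on the weaker strand of genes with few reads, it was 1.99 to 2.09 times as high near the replication origin as far from it in WT, and 1.35 to 1.48 times in ∆SI3*. Antisense reads numbered 29.1 ± 4.11 per 100 sense reads in WT and 12.6 ± 1.04 in ∆SI3* (exact permutation p = 0.1). With 3 libraries against 3, 0.1 is the smallest p this test can give. Reads in tRNA genes made up 7.70 ± 2.03% of the WT reads and 12.1 ± 2.21% of the ∆SI3* reads (exact permutation p = 0.2). The deposited values, which carry 1 scale factor per library, summed on average to 0.675 times as much in ∆SI3* as in WT (exact permutation p = 0.1). What that factor was scaled to is not given in the sources used here. If it was set from the spike-in, the deposited scale would be the absolute one, and the calls made after TMM scaling below would be relative only.

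Both asparagine synthetase genes stood out among the genes with higher nascent transcription in ∆SI3*. Signal in asnA (b3744), which encodes the ammonia-dependent enzyme, rose from 415 ± 28.4 to 11414 ± 543 CPM, a log2 change of 4.78 ± 0.10 (SE; limma adjusted p = 2.95e-08). Signal in asnB (b0674), which encodes the glutamine-dependent enzyme, rose from 354 ± 14.0 to 5502 ± 341 CPM (log2 change 3.95 ± 0.09, SE; adjusted p = 2.95e-08). The largest fall was in ilvC (b3774), which encodes the ketol-acid reductoisomerase of isoleucine and valine synthesis, from 5991 ± 573 to 1268 ± 214 CPM (log2 change -2.25 ± 0.15, SE; adjusted p = 2.09e-05). Of 54 ribosomal protein genes 42 were lower, and the set test of this list passed with a preset correlation (adjusted p = 8.39e-08) but not with an estimated one (adjusted p = 0.854). Genes of the heat shock and anaerobic respiration lists were more often higher than lower, while neither list passed the set test (adjusted p = 0.242 and 0.169). Of 2040 genes tested, 637 passed as higher and 600 as lower in ∆SI3* at a false discovery rate of 0.05, of which 69 and 46 changed at least 2-fold.

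Further rises fell in genes of several functions. The biofilm regulator gene bssR (log2 change 1.98), the methionine sulfoxide reductase gene msrB (1.95), the ribosome hibernation factor gene rmf (1.79) and the threonine synthase gene thrC (1.63) all rose. So did the small RNA genes istR (1.79), whose RNA represses a toxin gene, and sdsR (1.60). The small protein gene mntS rose by 1.74 on the log2 scale, from 222 ± 29.4 to 746 ± 111 CPM, and the little-characterised genes ydiH (1.73), ydcH (1.60) and ybfA (1.56) rose as well. Adjusted p-values in this group ran from 5.39e-06 for istR to 0.000339 for bssR.

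Among the falls, fhuF (b4367), which encodes a ferric siderophore reductase, went from 639 ± 43.2 to 151 ± 14.7 CPM (log2 change -2.07, adjusted p = 5.39e-06). The major fimbrial subunit gene fimA fell by 1.93 on the log2 scale, from 339 ± 134 to 83.8 ± 12.6 CPM. The guanidinium exporter gene gdx fell by 1.61, from 1319 ± 177 to 430 ± 50.0 CPM. The remaining genes of this group were yjaA (log2 change -1.74), yqcC (-1.66), yghE (-1.65), ygcW (-1.64), the small protein genes ynaL (-1.95), yqhJ (-1.92) and yjeV (-1.68), and fimR2 (-1.84), which is 35 nt long. Adjusted p-values in this group ran from 5.39e-06 for fhuF to 0.00169 for fimR2.

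**Figure D2:**
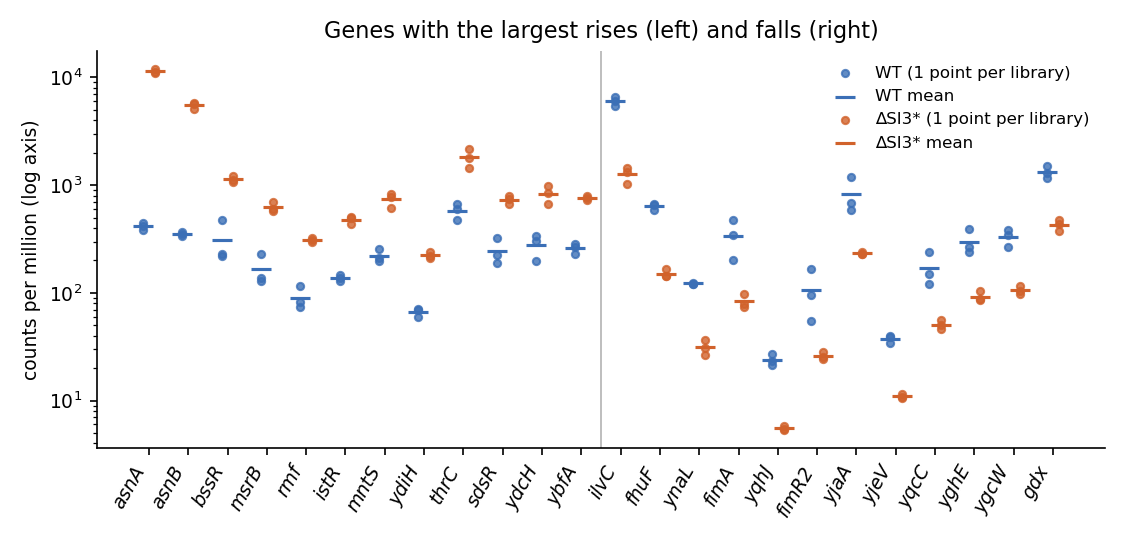
CPM (y axis, log scale) of the 12 genes with the largest rises (left of the line) and the 12 with the largest falls (right), 1 point per library and a bar at the mean of each strain. For asnA the means are 415 in WT and 11414 in ∆SI3*, and for ilvC they are 5991 and 1268.

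Genes of the translation apparatus were more often lower than higher. Of 54 ribosomal protein genes, 0 rose, 42 fell and 12 did not pass, and 44 fell when adjusted over the list alone. Examples were rplI (log2 change -0.96), rpsR (-0.96), rpmA (-0.89) and rpsT (-0.75), and the median of the list was -0.62. The limma camera set test gave this list an adjusted p of 8.39e-08 with a preset correlation, and adjusted p = 0.854 with an estimated correlation, which was 0.805 between these genes. Of 23 aminoacyl-tRNA synthetase genes, 5 rose and 10 fell, counts that stayed the same when adjusted over the list alone. The seryl-tRNA synthetase gene serS rose (0.88), and gltX (-0.65), proS (-0.81) and pheS (-0.51), which charge glutamate, proline and phenylalanine, fell. In the list of RNA polymerase subunits, sigma factors and elongation factors, 3 of 16 rose and 3 fell (2 and 3 when adjusted over the list alone). The stationary-phase sigma factor gene rpoS (0.81) and the antitermination factor gene nusB (0.56) rose, and the termination factor gene rho (-0.73) and the transcript cleavage factor gene greA (-0.37) fell.

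Iron uptake genes were the other list called by the set test, with an adjusted p of 0.00647 with a preset correlation but 0.854 with an estimated one. Of 9 measured members, 0 rose and 6 fell, or 7 when adjusted over the list alone, with a median log2 change of -0.73. Besides fhuF, these were the ferric citrate sigma factor gene fecI (-1.37), the enterobactin transport gene fepD (-1.12) and the bacterioferritin-associated ferredoxin gene bfd (-0.94). None of the other 19 lists tested this way passed, and the lowest adjusted p among them was 0.169, for anaerobic respiration and fermentation.

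Among stress lists, 8 of 15 heat shock genes rose and 1 fell, with the protease genes clpP (1.01), clpX (0.61) and htpX (0.68) and the small chaperone gene ibpA (0.86) among the rises. Of 11 cold shock genes, 2 rose and 5 fell: cspE (0.67) and the ribosome-associated inhibitor gene raiA (0.66) rose, and cspB (-1.22) and cspG (-0.88) fell. Of 11 genes of the RpoS general stress list, 5 rose and 5 fell, with osmE (0.63) on one side and the acid resistance genes hdeB (-1.32) and hdeA (-0.66) on the other. Of 11 envelope stress genes, 3 rose and 2 fell, among them rseA (0.51), which encodes the anti-sigma-E factor, and the response regulator gene cpxR (-0.80). Of 12 SOS genes, 3 rose and 1 fell: yebG (0.64), lexA (0.49) and recA (0.33) rose and the DNA polymerase II gene polB (-0.50) fell. With the floor of the background subtracted, lexA (0.28, adjusted p = 0.0562) and recA (0.23, adjusted p = 0.0548) did not pass. Of 11 oxidative stress genes, 5 rose and 3 fell, including thioredoxin 2 (trxC, 0.71), ahpF (0.37) and glutathione reductase (gor, -0.54). For each of these lists the counts were the same when adjusted over the list alone.

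Biosynthetic genes did not move as a block. In the amino acid operons with attenuators, 3 of 14 genes rose and 7 fell: thrC (1.63) and thrB (1.28) of the threonine operon rose, and hisG (-1.41), the start of the histidine operon, and ilvG (-0.83) fell. The annotation used here lists ilvG as a pseudogene, and the labels name an ilvG+ allele in both strains. Of 5 genes for arginine, methionine and cysteine, 3 rose and 2 fell, with the regulator gene cysB (0.80) and metK (0.35) higher and cysE (-0.68) and cysA (-0.49) lower. All 4 measured purine genes fell, among them guaB (-0.97) and guaA (-0.57) of guanine nucleotide synthesis. Of 4 pyrimidine genes, pyrG rose (0.36), upp fell (-0.66), and udp (-0.12) and pyrH (-0.11) did not pass. With the floor of the background subtracted, metK (0.24, adjusted p = 0.0619), cysA (-0.30, adjusted p = 0.176) and pyrG (0.21, adjusted p = 0.171) did not pass, and udp did (-0.27, adjusted p = 0.0488). All 4 measured genes of lipopolysaccharide operons with an ops element fell, for example glf (-1.22), rfbX (-1.13) and rfbA (-0.88), and the labels name an rfb mutation in both strains. Adjusting over each list alone gave the same counts for these 5 lists.

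In central metabolism, 7 of 16 glycolysis and phosphotransferase genes rose and 1 fell (6 and 1 when adjusted over the list alone), with pfkB (0.61), fbaA (0.48) and pgk (0.38) higher and pykF (-0.59) lower, though pgk did not pass with the floor of the background subtracted (0.19, adjusted p = 0.129). Of 11 TCA cycle genes, 4 rose and 1 fell, led by the citrate synthase gene gltA (0.83) and icd (0.55). Of 23 genes for ATP synthase and NADH dehydrogenase, 5 rose and 9 fell, with atpE (-0.92), atpF (-0.91) and atpH (-0.91) of ATP synthase lower and nuoC (0.43) higher. Of 17 genes for anaerobic respiration and fermentation, 10 rose and 2 fell, including the nitrate reductase gene napA (0.87), nirD (0.85), the alcohol dehydrogenase gene adhE (0.77) and dmsA (0.67). For the last 3 lists, adjusting over the list alone gave the same counts. Of 16 genes for the use of other sugars and amino acids, 1 rose and 7 fell (1 and 4 when adjusted over the list alone), with tdcA (-1.19), gatD (-0.71) and gatB (-0.57) lower.

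Of 21 genes for cell division and chromosome replication, 11 rose and 5 fell, or 12 and 7 when adjusted over the list alone. The DNA translocase gene ftsK (0.69) and ftsQ (0.55) rose, and the topoisomerase genes gyrB (-0.90) and parC (-0.61) fell. Of 18 nucleoid protein and global regulator genes, 10 rose and 3 fell, including fnr (0.82), ihfB (0.70) and dps (0.50) on the higher side and fis (-0.83) on the lower. Of 12 prophage and silenced genes, 5 rose and 4 fell, among them ymfL (1.08), dicA (0.91) and appY (-0.89). Of 12 leader peptide genes, 7 rose and 3 fell: thrL (1.47), hisL (1.32) and rhoL (0.85) rose and pyrL fell (-1.47). The only flagellar or chemotaxis gene that could be measured, cheW, had a log2 change of 0.07 (adjusted p = 0.486), and of 0.38 with the floor of the background subtracted (adjusted p = 0.0155). Adjusting over the list alone left the counts of the last 4 lists as they were.

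These tests were limma fits on log2 CPM after TMM scaling, which centres the genes, whereas on the deposited scale the median gene had a log2 change of -0.31, 42 genes passed as higher and 260 as lower, and 113 of the genes called higher had a negative value. Of the 118 genes named by rule, 48 lost their call on that scale, among them rpoS (log2 change 0.49), nusB (0.23), serS (0.55) and clpP (0.68). The fall of greA was larger there (-0.69), and its call was lost to the spread of the factors. Subtracting the background by distance from the origin left 513 genes higher and 490 lower. With it cspE, raiA, lexA, recA, metK, pyrG, fbaA and pgk lost their calls and cysA turned sign. On the deposited scale the medians of the glycolysis (-0.07), TCA cycle (-0.14), cell division (-0.02), nucleoid protein (-0.07), envelope stress (-0.16) and SOS (-0.26) lists were below 0, and those of the heat shock (0.08), anaerobic (0.05) and leader peptide (0.14) lists stayed above it.

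Pause sites were positions where 3′ ends piled up above their surroundings. In scored positions they were more numerous in ∆SI3*, where each library, thinned to 21427317 reads, held 19645 ± 66.2 sites in scored positions, against 16372 ± 569 in WT, a ratio of 1.2 (exact permutation test, two-sided, p = 0.1, the smallest possible). Per 1000 positions deep enough to be scored, this was 10.9 ± 0.0418 sites in ∆SI3* and 8.64 ± 0.282 in WT. The ratio was 1.69 with at least 30 reads required at a site and 1.62 in windows with a mean of at least 5 reads per position. Outside the scored positions, which include antisense strands and genes without a strand, the order was reversed: without thinning, 43394, 37625 and 57420 sites were called in WT and 26055, 21536 and 26218 in ∆SI3*. Those positions took 46.8, 49.5 and 52.7% of WT reads and 34.1, 32.3 and 33.2% of ∆SI3* reads, so thinning did not match the depth at scored positions.

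The strength of a site relative to its window changed at most sites, and more often upward. In the gene bcsE of the cellulose synthesis operon, the site at position 3696473 (+ strand) went from 1.41 ± 0.467 to 35.0 ± 3.29 times the mean of its window, with 50.7 ± 27.5 reads in WT and 1720 ± 314 in ∆SI3* (log2 change 4.69, adjusted p = 1.06e-05). Upstream of racC, a Rac prophage gene, the site at 1417481 (+ strand) went from 213 ± 125 to 6.58 ± 3.48 times its window (log2 change -4.99, adjusted p = 2.23e-05). Of 18927 sites found in at least 3 of the 6 libraries, 10035 in 1916 genes were raised in ∆SI3*, 2808 in 1389 genes were lowered and 6084 did not pass. At raised sites the median height over the window was 4.76-fold in WT and 14.4-fold in ∆SI3*, and at lowered sites it was 11.5-fold and 4.32-fold. The classes were set by this same height, so these medians describe them and are not a further result. Of the raised sites 5496 were called in no WT library, and of the lowered sites 2191 in no ∆SI3* library. Sites upstream of genes made up 12.6% of raised and 15.9% of lowered sites.

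The largest rises included sites inside yidA (position 3876939, - strand), which encodes a sugar phosphatase, at 0.742 ± 0.280 times its window in WT and 21.8 ± 4.00 in ∆SI3*. Others lay inside ydbK (1440560, - strand; log2 change 4.81), the diguanylate cyclase genes dgcF (1611824, - strand; 4.62) and dgcQ (2027912, - strand; 4.56), and lapA (1340332, + strand; 4.58). Upstream of genes, they lay before ygjP (3235942, + strand), at 2.61 ± 0.136 and 61.1 ± 2.09 times its window, and before yhhY (3581014, + strand; 4.78), pdeN (2270615, + strand; 4.64) and metJ (4128451, - strand; 4.49), which encodes the repressor of methionine synthesis. None of these 10 sites, bcsE included, was called in a WT library.

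The largest falls included the site upstream of panD (146762, - strand), the aspartate decarboxylase gene, at 14.0 ± 4.07 times its window in WT and 0.434 ± 0.137 in ∆SI3*. Inside ribB (3184398, - strand), a riboflavin synthesis gene, the site went from 13.9 ± 0.721 to 0.641 ± 0.0642 times its window, and inside hemA (1263963, + strand), a haem synthesis gene, from 12.6 ± 0.0642 to 0.599 ± 0.200. Sites also fell inside ybaP (508041, - strand; log2 change -4.73), aroB (3517499, - strand; -4.67), rflP (1791728, - strand; -4.64) and tsaE (4395841, + strand; -4.57). The site in insI3 (4508487, - strand; -4.58) lies in an insertion element, and the site at 4188733 in rpoC lies inside the deleted stretch.

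**Figure D3:**
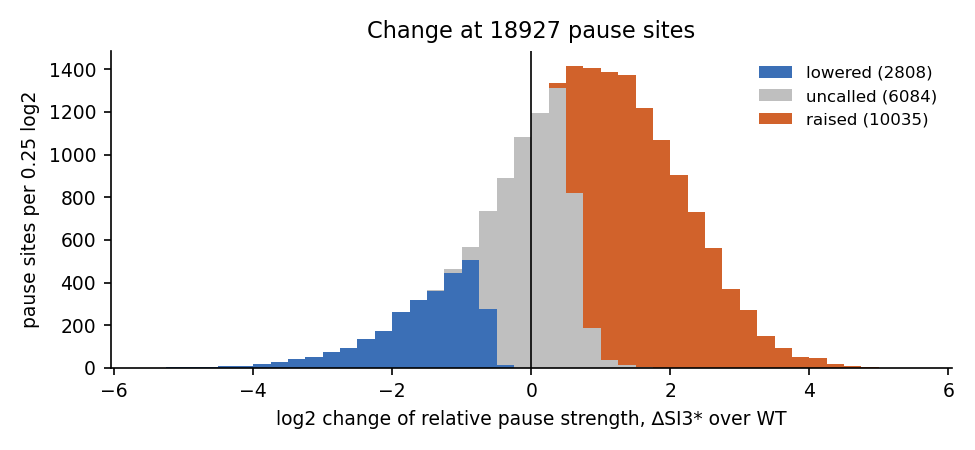
Number of pause sites (y axis) by log2 change of the site relative to its window (x axis, bins of 0.25), coloured by call and stacked. Raised sites number 10035, lowered sites 2808 and uncalled sites 6084, and most of the distribution lies above 0, with a median of 0.78.

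The median log2 change over all sites was 0.78 (per-library medians, exact permutation p = 0.1). It was 0.28 at the 3752 sites called in all 6 libraries with the floor of the background subtracted, and 0.19 at 2718 of them with the background subtracted by distance from the origin. With that subtraction at all sites 5770 of 11684 were raised and 2379 lowered, with a median of 0.60. Without the window as an offset 6050 sites were raised and 5658 lowered, with a median of 0.06. That setting is scaled on the reads at the sites themselves, which centres the sites, so it cannot show a general rise or its absence.

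Where pause sites lay next to each other, ∆SI3* had more of its reads at the downstream one. Upstream of cfa, which encodes a fatty acid cyclopropane synthase, the downstream position of the pair 1741363 and 1741364 (+ strand) held 26.2 ± 6.02% of the reads of the pair in WT and 68.4 ± 1.60% in ∆SI3*. In rob, a regulator gene, it held 27.4 ± 3.80% and 58.9 ± 3.32% (positions 4635103 and 4635102, - strand), and in ycbJ 18.2 ± 7.08% and 59.5 ± 2.24% (971763 and 971764, + strand). The small RNA gene oxyS went from 40.9 ± 2.00% to 55.9 ± 1.16%. The opposite shift was found in the small RNA gene glmY, from 72.3 ± 1.67% to 60.9 ± 0.896%, and pairs upstream of rpsJ (32.0 ± 2.10% and 33.2 ± 0.998%) and aceE (50.4 ± 9.66% and 50.0 ± 2.96%) did not pass. These pairs were chosen after the values were seen from the 12 with the most reads, of which 5 shifted toward downstream, 1 shifted toward upstream and 6 did not pass. Reads of finished and of nascent RNA were not separated here, so the ends in small RNA genes such as oxyS and glmY need not mark a polymerase.

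Of 1754 pairs of sites 1 nt apart, in 1101 genes, 1272 shifted toward the downstream position in ∆SI3* and 33 toward the upstream one. The median share of reads at the downstream position was 40.5 ± 2.29% in WT and 64.2 ± 1.78% in ∆SI3* (exact permutation p = 0.1). A second site lay 1 nt downstream of 24.3% of lowered sites, 13.4% of uncalled sites and 2.52% of raised sites. The odds ratio of lowered to raised sites was 12.4 (95% confidence interval 10.7 to 14.5, Fisher's exact test over sites, p = 1.17e-268, with sites that are not independent replicates). The classes rest on the same reads as the pairs, and the window of a site includes its neighbour. The odds ratio therefore restates the shift in pairs and is not separate support for it. Pairs 2, 3 and 4 nt apart shifted the same way, with 320 of 527, 191 of 315 and 143 of 241 toward downstream and 57, 49 and 39 toward upstream. Pairs 5, 6, 7 and 8 nt apart were less one-sided, with 56, 60, 43 and 22 toward downstream and 51, 32, 29 and 27 toward upstream. Pairs 9 and 10 nt apart went the other way more often, with 41 of 89 and 73 of 196 shifted toward upstream and 19 and 42 toward downstream. The comparison used positions only, since the base sequence around sites was not analysed here.

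**Figure D4:**
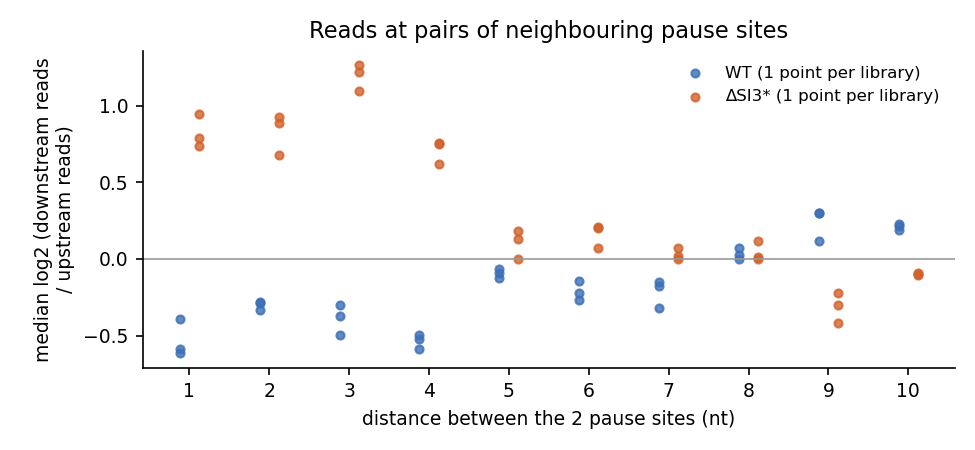
Median log2 ratio of reads at the downstream to reads at the upstream site of a pair (y axis) by the distance between the sites in nt (x axis), 1 point per library. At 1 nt the mean of the library medians is -0.53 in WT and 0.82 in ∆SI3*, and at 10 nt it is 0.21 and -0.10.

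Leader regions of attenuated operons held more signal relative to the gene that follows in ∆SI3*. The ratio of hisG to its leader hisL, in reads per nt, was 0.103 ± 0.00990 in WT and 0.0155 ± 0.00247 in ∆SI3* (log2 change -2.73, limma adjusted p = 6.42e-14). The ratio of ilvG to ilvL fell by 1.62 on the log2 scale (adjusted p = 1.82e-09), that of the termination factor gene rho to rhoL by 1.58 (2.14e-09), that of the magnesium transporter gene mgtA to mgtL by 0.65 (0.000873), and that of thrA to thrL by 0.44 (0.0167). The ratio of pheS to pheM had a log2 change of -0.04 (adjusted p = 0.812). All of these p-values rest on 1 variance pooled over the pairs (SE of 0.164 for each), not on the spread of each pair alone. These 6 of the 12 fixed pairs had a strand that could be read from the data for both members, and 5 fell. With the floor of the background subtracted, and also without ∆SI3* replicate 2 or replicate 3, the thrA ratio did not pass and 4 fell.

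**Figure D5:**
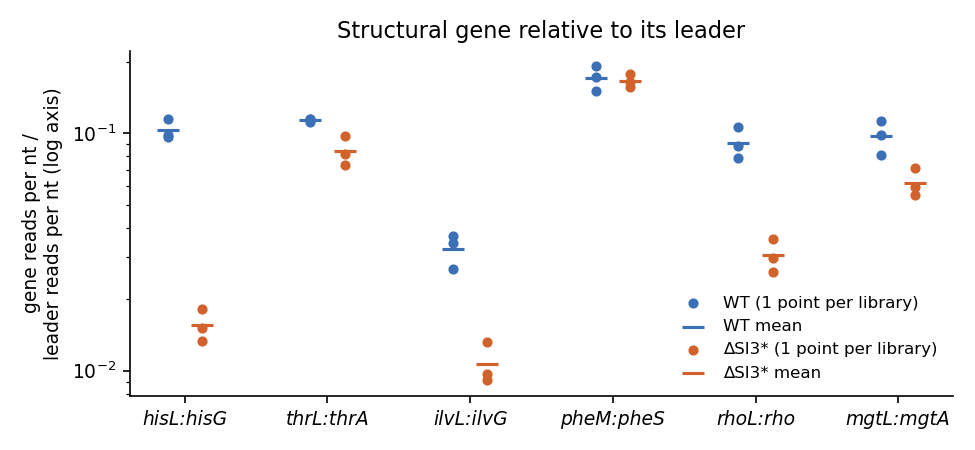
Reads per nt in the gene divided by reads per nt in its leader (y axis, log scale) for the 6 leader and gene pairs, 1 point per library and a bar at the mean of each strain. The hisG ratio is 0.103 in WT and 0.0155 in ∆SI3*, and the pheS ratio is 0.171 and 0.166.

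Within the his leader region, the site 20 nt past the end of hisL (position 2090066, + strand) stood at 18.9 ± 4.1 times its window in WT and 3.65 ± 0.174 in ∆SI3*. This position was chosen after the values were seen, and it was not among the sites found in at least 3 libraries. The site at 2090117, which was, went from 57.3 ± 15.5 to 23.2 ± 5.51 times its window (log2 change -1.30, adjusted p = 0.00104), while its reads numbered 2304 ± 1091 in WT and 2191 ± 935 in ∆SI3*, so the fall came with more reads in the window. Of 12 sites in or upstream of hisL and hisG, 4 were raised, 5 were lowered and 3 did not pass. The raised ones included 2089851 upstream of hisL, from 25.2 ± 3.42 to 50.7 ± 15.9 times its window (log2 change 0.96, adjusted p = 0.00766), and 2090344 in hisG (1.13, adjusted p = 0.00332). Inside trpL no site was called, and its reads numbered 39 to 74 per library. Upstream of trpL, the site at 1323209 (- strand) was raised (log2 change 1.96, limma adjusted p = 0.00104), with 6 ± 2 reads in WT and 25.7 ± 3.06 in ∆SI3*. The site at 1323257 (- strand) did not pass. The sites fixed beforehand by sequence in the his leader and at the ops elements were not analysed here.

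Along genes, asnA had 31.4 ± 1.79% of its reads in the first 150 nt in ∆SI3* and 19.1 ± 1.42% in WT (log2 change 0.96, limma adjusted p = 1.10e-06). Antisense reads in asnA equalled 64.8% of its sense reads in WT and 1.21% in ∆SI3*. A background spread evenly over the gene would pull the WT share toward an even one, and no background was subtracted from these shares. The share also rose in napA, with a log2 change of 0.37 (adjusted p = 0.0133), and in serS, from 33.7 ± 2.96% to 40.4 ± 1.86% (0.42, adjusted p = 0.00918). It fell in hisG, from 71.3 ± 3.65% to 53.2 ± 1.34% (log2 change -1.13, adjusted p = 1.01e-05), and in rho, from 30.9 ± 2.94% to 25.2 ± 0.762% (-0.40, adjusted p = 0.00646). These 5 genes were taken from the genes named above after the values were seen. Of 1177 genes at least 600 nt long, 527 had a higher share in ∆SI3* and 153 a lower one, and among the 879 genes at least 5 times above the floor of the background 397 were higher, or 319 with the floor of the background subtracted.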

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

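Of the tests in this part, the ones on the weaker strand, on sites called in all libraries and on pairs in deep windows were chosen after the results were seen, as were the splits of the libraries. The slope test was written down before its value was known. The tests of subtraction by distance from the origin and of tRNA peaks were chosen after related results were seen, with their bounds written before their own values were known.

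Outside the scored positions, the + strand position 3928242, just downstream of asnA, held 43 ± 9 reads in WT and 3518 ± 184 in ∆SI3* (SD, n = 3), a ratio of 81.8. It was found among the 40 unscored positions with the most reads, by a rule set after the data were seen: a mean at least 10-fold above WT, with no overlap between libraries. Because the rule asks for this, the difference was not tested. Signal in asnA itself rose from 415 ± 28.4 to 11414 ± 543 CPM, so the position was not shown to change apart from the gene.

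The background signal on both strands was higher in WT, with a floor equal to 26.6 ± 2.25% of WT reads and 13.7 ± 1.07% of ∆SI3* reads. Reads of another origin would add evenly along the chromosome, and against them as the whole cause, the excess of WT libraries on the weaker strand of genes with few reads was 2.99 to 3.19 times as high near the replication origin as far from it. Copies of sense reads stay open, since log2 antisense changes followed log2 sense changes over 2018 genes with a slope of 0.295 (0.271 to 0.334 with 1 library left out in turn), between the values set for and against. DNA carried into the libraries stays open too: within equal groups of genes by distance from the replication origin, the genes with most reads had a median of 1.24 to 1.33 times the weaker-strand density of genes with fewer reads in WT libraries, where DNA alone would give close to 1. A difference in antisense transcription between the strains may also contribute, and was not tested.

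Pause sites stood higher above their windows in ∆SI3*, with a median log2 change of 0.78. If the background of WT alone had filled its windows, subtracting all of it would have removed the change, and the median was 0.60 after subtraction by distance from the origin. That background came from genes with few reads. At equal distance, genes with most reads had a median of 1.24 to 1.33 times this density on their weaker strand in WT and 1.48 to 1.53 times in ∆SI3*. Too little may thus have been subtracted, and the value does not exclude this cause. If sites had been picked mostly from ∆SI3* libraries, sites called in all 6 libraries would show none, and their median was 0.44. With both corrections together the median of the changes over sites was 0.19, which lies between the values set for and against. The median log2 strength per library, another measure, was -3.50 ± 0.0488 in WT and -3.22 ± 0.0214 in ∆SI3* (n = 3). By both measures ∆SI3* stayed higher, so the corrections made the change smaller and did not remove it. Whether the background and the choice of sites account for the rest stays open. Stronger pausing by the ∆SI3* polymerase was not tested apart from them and stays open too.

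In pairs of sites 1 nt apart, reads lay more often at the downstream position in ∆SI3*. A difference between strains in where reads were trimmed would move all RNA ends alike, and at the main peak of 70 tRNA genes the median log2 ratio of reads 1 nt downstream to reads at the peak changed by -0.61 (WT -6.09 ± 0.322 and ∆SI3* -6.70 ± 0.197, SD, n = 3), against a rise of 1.35 at pause sites. The background of WT would matter less in deep windows, where 24.6 pairs shifted toward downstream for each that shifted toward upstream. Pairs 2 to 4 nt apart shifted the same way and pairs 9 to 10 nt apart the opposite way, so the shift was not special to 1 nt. A change in where the ∆SI3* polymerase pauses or how far it backtracks may be the source, and no test here separates these. Loss of SI3 and the further amino acid change cannot be told apart either.

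The 6 libraries can be split into groups of 3 in 10 ways, which is too few for a share under 0.05. The real split called 1237 genes and the highest other split 0, and in this and the next 4 results 1 split, the real one, gave as many. The values were 12843 and 0 for pause sites, 1305 and 0 for pairs 1 nt apart, 680 and 0 for 5′ shares, and 5 and 0 for leader pairs. For gene lists the real split called 2 and the highest other 7, and 9 of the 10 splits gave as many.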

How the results depend on the processing

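Alternatives chosen after seeing the data were the deposited scaling, other pseudocounts, edgeR on recovered reads, subtraction of the background by its floor or by distance from the origin, genes at least 5 times above the floor, windows with a mean of at least 5, centring, sites called in all 6 libraries, sites per scored position and the strand taken from the leader. With the deposited scaling, 42 genes were higher and 260 lower in place of 637 and 600, so the balance moved toward lower, and 113 genes called higher turned sign. This scaling changes only the factor per library, and the spread of that factor enters the test. With an estimated correlation, 0 lists passed in place of 2. With fewer sites tested, 5026 were raised and 1252 lowered at 6 SD (median log2 change 0.90), 4177 and 1076 in windows with a mean of at least 5 (0.92), and 1746 and 310 at sites called in all 6 libraries (0.44). With at least 30 reads 1729 were lowered (median 0.93), and with sites of the pooled profile 1678. Without the window offset 6050 were raised and 5658 lowered (median 0.058), and after centring 5943 and 5421 (0.081). Both settings centre the sites, the former by scaling on the site reads themselves, so a median near 0 was set in advance. The median was 0.64 with the floor of the background subtracted and 0.28 for sites called in all 6 libraries with it subtracted. Subtracted by distance from the origin, with fewer sites tested, 5770 were raised, and the medians were 0.60 and 0.19. For pairs 1 nt apart, 441 shifted toward downstream and 7 toward upstream at 6 SD, and 491 and 20 in windows with a mean of at least 5, with fewer pairs tested. With the floor of the background subtracted 319 of 879 genes had a higher 5′ share, against 397 of the same genes without subtraction, and with the strand taken from the leader 10 of 12 leader pairs were lower. The cause of the other changes was not tested.

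With each library left out in turn, 543 to 675 genes were higher and 489 to 656 lower, 2 lists were lower, 9193 to 10112 sites were raised and 2517 to 2675 lowered, and the median log2 change was 0.73 to 0.84. Pairs toward downstream numbered 1180 to 1249 and toward upstream 27 to 37, the odds ratio was 12.1 to 15.5, the ratio of sites per library 1.18 to 1.22, 461 to 537 genes had a higher and 129 to 155 a lower 5′ share, and 4 to 5 leader pairs were lower. The thrA to thrL ratio was the one that missed the threshold, with the floor of the background subtracted and without ∆SI3* replicate 2 or 3. After subtraction, 504 of the genes called higher and 501 of those called lower were called again, and 13 called genes had the opposite sign. Of 118 named genes, 48 lost their call with the deposited scaling and 6 with the floor of the background subtracted, and over all settings 72 calls were lost and 2 gained. For named sites the outcome was the same in all 333 cases, and for leader pairs 3 calls were lost, 1 of them with the floor of the background subtracted. Among named results that had a call only cysA turned sign, to 0.23 (without a call), with the background subtracted by distance from the origin, which took the calls of 8 other genes. Deviations of same-numbered libraries correlated over genes by 0.026, 0.54 and 0.34 and over sites by 0.009, 0.048 and 0.069, and the highest value between different numbers was 0.221 over genes, so replicates 2 and 3 may share a batch over genes and replicate 1 shows no such sign. The labels do not pair the samples. A replicate block, which allows for such pairing, gave 674 genes higher and 641 lower, 10066 sites raised and 2829 lowered, 1266 and 31 pairs, 563 and 169 genes by 5′ share, 5 leader pairs and 2 lists. Omitting the filter removed or added no gene. The spike-in ratio and scaling and the tests on base sequence were not run. Simulated 1.5-fold changes were recovered at 0% of sites, in data where 18727 of 18927 sites were unchanged. With so few changed sites the adjusted threshold was stricter than in the real data. The simulation thus does not give the power of the real calls, and depth was not varied.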

Other observations

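The counts of small RNA genes and the tests on amino acid shortage and on leaders with a strand taken from the leader were chosen after the results were seen. The test on distance from the replication origin was written down before its value was known.

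Small RNA genes were higher in ∆SI3* more often than lower. Of 95 ncRNA genes with an assigned strand, 50 rose and 14 fell, with a median log2 change of 0.35, while of 34 pseudogenes 6 rose and 8 fell (limma). Over all 2040 genes 637 rose and 600 fell. The group was not tested as a set, and its values are after TMM scaling, while on the deposited scale the median of all genes was -0.31. The genes named here were chosen after their values were seen. Signal in csrB, whose RNA binds the regulator CsrA, rose from 2640 ± 692 to 5788 ± 467 CPM (log2 change 1.16), and in glmY, whose RNA acts on amino sugar synthesis, from 1136 ± 146 to 2517 ± 445 CPM (1.14). Falls included micF, which targets the porin gene ompF (log2 change -1.05), gcvB, which targets peptide transport genes (-0.94), and ryhB, which acts under iron limitation (-0.80), from 326 ± 67.6 to 185 ± 3.49 CPM. Reads in tRNA genes, another class of stable RNA, went from 7.70 ± 2.03% to 12.1 ± 2.21% of all reads (exact permutation p = 0.2), and reads of finished and of nascent RNA were not separated here.

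Further leader pairs could be measured when a gene took the strand of its leader. The ratio of ilvB to ivbL fell by 1.93 on the log2 scale, from 0.107 ± 0.0163 to 0.0283 ± 0.00430, and those of leuA to leuL and pheA to pheL fell by 0.64 each. The ratio of tnaA to tnaC fell by 0.53 and that of trpE to trpL by 0.77, where trpE lay at 0.964 times the floor of the background in WT. The ratio of pyrB to pyrL had a log2 change of 0.32 (limma adjusted p = 0.130).

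Genes near the replication origin were lower in ∆SI3* relative to genes far from it. The median log2 change was -0.20 in the 408 genes nearest the origin and 0.11 in the 408 farthest, a difference of -0.32 (95% bootstrap interval -0.41 to -0.23). The interval measures spread over genes and not between cultures. The difference was -0.27 without ribosomal protein genes, -0.61 after the floor of the background was subtracted and -0.42 after subtraction by distance from the origin. The background itself was 1.99 to 2.09 times as high near the origin as far from it in WT and 1.35 to 1.48 times in ∆SI3*, so it moved along with the gene values. A lower ratio of origin to terminus copies in ∆SI3*, as in slower-growing cells, may be the source, though DNA was not measured and a change in transcription with the same layout is open. Of the ribosomal protein genes, 36 lie in the group nearest the origin, and their median went from -0.62 to -0.51 after a straight line on distance was removed.

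Of 54 ribosomal protein genes 42 fell while asnA and asnB rose, which a general response to amino acid shortage could give. The set test of the ribosomal list passed with a preset correlation only (adjusted p = 0.854 with an estimated one), and 9 of 10 splits of the libraries called as many lists. A shortage would also raise amino acid biosynthesis genes, and the camera set test of both fixed lists of them leaves this open. Its direction was down for the operons with attenuators (adjusted p = 0.242), against such a rise, and up for the other list (adjusted p = 0.787). The operons with attenuators had 3 genes higher and 7 lower, and the list for arginine, methionine and cysteine had 3 higher and 2 lower with only 5 of its 31 genes measured. A shortage of asparagine alone, or a change at the asn genes themselves, was not tested.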
